A study of Arabidopsis thaliana with 6 samples.

How the data were processed

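Per the labels, 10-day-old Col-0 seedlings grown in short days were treated for 8 h with 3-OH-C10:0 or DMSO, total RNA was extracted with TRIzol, checked on a Bioanalyzer and sequenced on a HiSeq2500. Library strandedness and read length are not given in the sources used here, so antisense transcription was not separated. The dose is given as 5 microM in the sample characteristics and as 5 mM in the treatment protocol, and no value here depends on it. The 6 samples were taken as 2 groups of 3 libraries from the labels.

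The tools were, per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.2.4, StringTie 1.3.1 and RSEM, whose version is not given in the sources used here, and the build was TAIR10. What each tool did and in which order is not given in the sources used here. The estimated counts per locus were made by the authors with tools among these and deposited without normalisation, per the file headers, which name them counts. Of these values 3.618% were not whole numbers, so they were treated like the expected counts of RSEM and rounded here to the nearest whole number. The FPKM values, fragments per kilobase scaled to library depth, were computed by the authors and used as deposited. Over 2522 loci with at least 1000 estimated counts in every library, the length implied by count and FPKM had a median ratio of largest to smallest library of 1.0002, and the FPKM of a library summed to between 702210 and 743531.

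The files held 28259 loci, of which 27416 carried an Arabidopsis locus code and 843 were assembled loci without one. Of the coded loci 26719 were found in the TAIR10.1 annotation. The files carry no coordinates, so chromosome, start, end, strand and exon blocks are those of TAIR10.1, matched by locus code. Exon blocks are merged over all transcripts of a gene. The tables held 88 plastid and 122 mitochondrial loci, and 4677 loci had no count in any library. Estimated counts summed to 19390988, 21000782 and 20816749 in DMSO replicates 1 to 3 and to 20382242, 18064723 and 27131500 in treated replicates 1 to 3. Raw reads were not used here.

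Genes were kept by filterByExpr of edgeR with a minimum count of 10, which left 19768. Libraries were scaled by the trimmed mean of M values (TMM). Dispersions were estimated with the default settings of edgeR, and the quasi-likelihood fits were robust. The quasi-likelihood F test compared treated with DMSO seedlings, two-sided, without a replicate block. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are said to have risen or fallen. Standard errors were derived from the log2 fold change and the F statistic. The common biological coefficient of variation was 11.3%. CPM values were scaled by TMM without prior counts. For a group without counts, folds are lower bounds against a floor of 3 counts over that group, and for a group with 1 to 3 counts the ratio has a 95% counting interval.

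The 27 gene lists held 489 loci and covered NADPH supply, NADPH oxidases, immune receptors and signalling, markers of pattern-triggered immunity, salicylic acid, jasmonate, ethylene, tryptophan-derived defence, aliphatic glucosinolates, antioxidants, chemical detoxification, beta-oxidation, fatty acid synthesis, phenylpropanoids and lignin, flavonoids and anthocyanins, photosynthesis, the circadian clock, heat and protein folding, abscisic acid and cold, hypoxia, auxin and growth, carbon and nitrogen status, cell division, senescence, root tissue, guard cells and vascular tissue. Members that did not pass the filter on low counts were counted as not measured. Each list was tested against the other genes with camera of limma at an inter-gene correlation of 0.01, beside it with an estimated correlation, and with fry, each adjusted over the 27 lists. For the DESeq2 Wald test, limma on FPKM and the GC and length correction, camera was run in its preranked form on gene statistics. List results of those settings thus differ from the main setting in the form of the test as well. Members were also adjusted over the list alone. Where a median or mean is given it is over all measured members.

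Genes were named by a rule fixed before the data were examined. It took the 12 highest and the 12 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 20 counts in the higher group and all 3 treated libraries on the same side of all 3 DMSO libraries. From each list that passed the set test or had 2 or more members past the gene test it took up to 4 members with the smallest p. It always took 12 genes: LORE, RIPK, NADP-ME1 to NADP-ME4, RBOHD, RBOHF, BIK1, FRK1, PR1 and PAD3. Not every gene that the rule took is named in the Results. Genes named beyond the rule were chosen after their values were seen: members that did not pass or went against their list, further members of a list, genes that stood apart in a single library and examples from gene families.

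Library composition was compared by exact permutation tests over all 20 assignments of 3 against 3 libraries, two-sided, whose smallest possible p is 0.1. Between-library agreement was measured by Pearson correlation of log2 CPM and by the mean chi-square per gene against sampling noise. The labels do not say that a replicate number marks a shared day or batch, so the main fit was fixed without a block. As a check, residuals of libraries with the same replicate number did not correlate above 0.1 (0.0264, -0.0159 and 0.0994). With 3 libraries per group this check is weak.

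Alternatives fixed before the data were examined were size factors of DESeq2, no filter on low counts, a minimum count of 50, the Wald test of DESeq2, a block for the replicate number, limma with trend on log2 FPKM with pseudocounts of 1, 0.1 and 0.01 over genes with FPKM of at least 1 in at least 3 libraries, leaving out organelle loci, leaving out each library, thresholds of an adjusted p under 0.01 and of at least 2-fold, and the other set tests. Chosen after the data were examined were total-count scaling, leaving out assembled loci, a loess correction (span 0.5) of each library on GC content and log2 exon length, which were known for 98.35% of the tested genes, list counts without treated replicate 3 and without DMSO replicate 1, and tests on 24 gene families grouped by product name. Bootstrap intervals of medians used 2000 draws.

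The gene test was tested on simulated data with the dispersions of these libraries, 19768 genes and 200 changed genes. It recovered 83 (85.57%) of the 2-fold and 94 (96.91%) of the 4-fold changes among 97 tested genes each. Beside these it made 19 false calls, a larger share of all its calls than the adjusted p threshold of 0.05 is meant to allow. In a simulated set test a list of 25 members shifted by a log2 of 1 was called, and 1 of 100 random lists was called. Both simulations drew genes independently and changed few of them. They therefore do not show how the tests behave when most genes change or when members are correlated. In these data the estimated correlation reached 0.692, for flavonoids and anthocyanins.

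The tools used here were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.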

Results

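Transcript levels were measured by RNA-seq in whole Arabidopsis thaliana seedlings of the Columbia (Col-0) ecotype. The seedlings were 10 days old, had grown in short days (10 h light, 14 h dark) and had stood overnight in water under light. The water was then replaced with 3-hydroxydecanoic acid (3-OH-C10:0) or with the solvent dimethyl sulfoxide (DMSO), and the seedlings were collected 8 h later. 3-OH-C10:0 is a medium-chain 3-hydroxy fatty acid of bacterial origin that Arabidopsis senses through the lectin receptor kinase LORE. The sample characteristics give the dose as 5 microM and the treatment protocol gives it as 5 mM, so the concentration is left open here. Each group held 3 libraries. The estimated counts summed to 19390988, 21000782 and 20816749 in the DMSO libraries and to 20382242, 18064723 and 27131500 in the treated libraries. In a single library 3 counts corresponded to between 0.111 and 0.166 CPM (counts per 1e6 counts). Intervals and floors given here cover counting error only. The sources used here do not say whether the replicates came from separately grown seedlings, so the p-values measure only the spread between these samples. Unless stated otherwise, values are mean CPM ± SD (n = 3 per group), scaled by the trimmed mean of M values, and log2 fold changes are treated over DMSO ± standard error. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 19768 tested genes. The comparison, the tests, the 27 gene lists and the rule for naming genes were fixed before the data were examined. Not every gene that the rule took is named here, and members named beyond it were chosen after their values were seen.

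The series addresses the receptor-like cytoplasmic kinase RIPK, NADP-malic enzyme 2 and the NADPH used to make reactive oxygen species, and the comparison of treated with control seedlings shows how the transcripts of that pathway stood 8 h after the elicitor. RIPK transcripts rose from 10.7 ± 0.291 to 116 ± 11.2 CPM (log2 fold change 3.43 ± 0.0992, adjusted p = 7.0e-10). NADP-ME2, a cytosolic malic enzyme that makes NADPH, was already abundant and rose from 590 ± 22.5 to 1401 ± 107 CPM (1.25 ± 0.112, adjusted p = 2.6e-06). RBOHD, the plasma membrane NADPH oxidase of the immune oxidative burst, rose from 29.6 ± 6.17 to 252 ± 11.1 CPM (3.09 ± 0.142, adjusted p = 2.8e-08), and LORE itself rose from 38.1 ± 8.34 to 142 ± 19.0 CPM (1.90 ± 0.168, adjusted p = 1.3e-05). BIK1, another receptor-like cytoplasmic kinase of immune receptor complexes, rose from 54.7 ± 10.1 to 167 ± 15.9 CPM (1.61 ± 0.137, adjusted p = 3.6e-06).

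Of the other malic enzymes, 1 rose and 2 did not pass. NADP-ME4, the plastid enzyme, stood at 347 ± 20.09 CPM in DMSO and 338 ± 29.1 CPM in treated seedlings (log2 difference -0.04 ± 0.101, adjusted p = 0.738). NADP-ME1 rose at a level close to the counting floor, from 0.333 ± 0.0368 to 0.820 ± 0.268 CPM (1.27 ± 0.387, adjusted p = 0.0128), a call that was lost without treated replicate 2 (adjusted p = 0.0563). NADP-ME3 was at 1.22 ± 0.0928 and 0.750 ± 0.274 CPM (-0.73 ± 0.318, adjusted p = 0.0596), and it passed the threshold as lower under total-count scaling (0.0417), under the correction for GC content and length (0.0349) and without treated replicate 2 (0.0213). Whether these changes differ from that of NADP-ME2 was not tested. On the 20-gene list of NADPH-supplying enzymes and NAD kinases, 9 members rose, 3 fell and 8 did not pass, with the same 9 and 3 adjusted over the list alone. G6PD6, a cytosolic glucose-6-phosphate dehydrogenase, rose from 27.5 ± 1.48 to 133 ± 6.68 CPM, PGD2, a 6-phosphogluconate dehydrogenase, from 114 ± 4.04 to 446 ± 27.03 CPM, and the NAD kinase NADK1 from 27.2 ± 0.438 to 48.3 ± 1.19 CPM. The plastid enzyme G6PD1 fell by 1.15 on the log2 scale, and an organellar isocitrate dehydrogenase fell by 0.48 and the glyceraldehyde-3-phosphate dehydrogenase ALDH11A3 by 0.43. As a list the NADPH-supplying genes did not pass the set test (camera adjusted p = 0.244). Without DMSO replicate 1 the count of members that fell went from 3 to 5.

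Of 8 measured NADPH oxidases, 6 rose and none fell, with 6 adjusted over the list alone. RBOHF rose from 18.8 ± 0.245 to 29.0 ± 1.33 CPM (0.63 ± 0.0810), RBOHE from 5.53 ± 0.187 to 10.4 ± 1.48 CPM and RBOHA from 2.26 ± 0.127 to 5.21 ± 0.827 CPM. RBOHB (0.41, adjusted p = 0.26) and RBOHC (-0.12, adjusted p = 0.53) did not pass. The list test gave an adjusted p of 0.114 with camera. After the correction for GC content and length it was 0.0283, with the preranked form of camera on gene statistics. The form of the test changed along with the correction, so the change cannot be credited to the correction alone. Among 24 genes of immune receptors and early signalling, 22 rose and none fell, with 22 adjusted over the list alone (median log2 fold change 1.205, camera adjusted p = 1.0e-09, adjusted p = 0.116 with an estimated correlation). They included the co-receptors SOBIR1 (30.5 ± 2.88 to 292 ± 7.65 CPM) and BAK1 (69.8 ± 0.930 to 300 ± 9.67 CPM), the LysM receptor kinase CERK1 (23.6 ± 1.25 to 150 ± 13.1 CPM) and the kinases MPK3 and MPK6 (log2 fold changes 1.27 and 1.29). The members that did not pass were the flagellin receptor FLS2 (-0.23, adjusted p = 0.084) and the kinase PBL35 (0.05, adjusted p = 0.633).

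**Figure D1:**
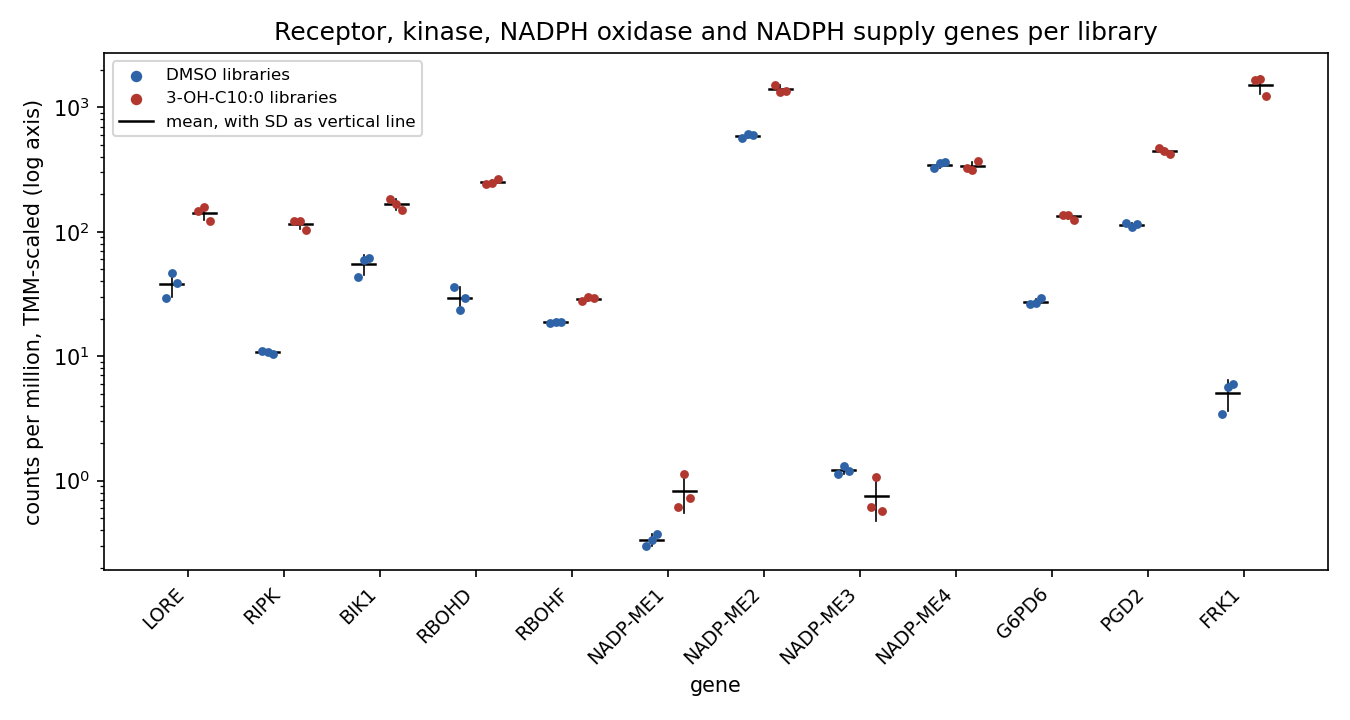
Normalised level of LORE, RIPK, BIK1, RBOHD, RBOHF, NADP-ME1 to NADP-ME4, G6PD6, PGD2 and FRK1, in CPM on a log axis. Other genes named in the text from the receptor, kinase, NADPH oxidase and NADPH supply groups are not drawn. Each point is 1 library (3 DMSO and 3 treated), horizontal lines are group means and vertical lines 1 SD. The treated libraries lie above the DMSO libraries for all genes drawn except NADP-ME3 (means 1.22 and 0.750 CPM) and NADP-ME4 (347 and 338 CPM).

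In the annotation of the TAIR10.1 assembly, LORE (AT1G61380) lies on the minus strand of chromosome 1 from 22645923 to 22650072 with 8 exon blocks, RIPK (AT2G05940) on the minus strand of chromosome 2 from 2287238 to 2289636 with 4, BIK1 (AT2G39660) on the plus strand of chromosome 2 from 16531527 to 16533986 with 6 and RBOHD (AT5G47910) on the plus strand of chromosome 5 from 19397041 to 19402061 with 8. RBOHF (AT1G64060) lies on the plus strand of chromosome 1 from 23769774 to 23776984 with 14 exon blocks. NADP-ME2 (AT5G11670) lies on the plus strand of chromosome 5 from 3754091 to 3758342 with 19 exon blocks, NADP-ME1 (AT2G19900) on the minus strand of chromosome 2 from 8591808 to 8595559 with 19, NADP-ME3 (AT5G25880) on the plus strand of chromosome 5 from 9024334 to 9028395 with 17 and NADP-ME4 (AT1G79750) on the minus strand of chromosome 1 from 30007288 to 30011690 with 18. FRK1 (AT2G19190) lies on the minus strand of chromosome 2 from 8326049 to 8329944, PR1 (AT2G14610) on the minus strand of chromosome 2 from 6241640 to 6242541 and PAD3 (AT3G26830) on the plus strand of chromosome 3 from 9887917 to 9889791. All counts are over whole genes, so no value refers to a single exon or untranslated region.

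The treatment was accompanied by a change in most of the measured transcriptome. Of the 19768 tested genes, 7036 rose and 7084 fell (71.4%), of which 3107 and 2913 changed at least 2-fold, and 783 rose but only 45 fell at least 8-fold. The values of the 3 treated libraries and the 3 DMSO libraries did not overlap for 15001 genes (75.9%, against 10% by chance). The first principal component held 91.4% of the variance and separated the groups. The 10 most abundant genes took 9.41% ± 0.357 of the counts in DMSO and 4.79% ± 0.0831 in treated libraries (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 samples allow). The small subunit gene of Rubisco, RBCS1A, was the most abundant transcript of each DMSO library, with 1.83% to 1.96% of its counts. Same-group libraries correlated with Pearson r of 0.986 to 0.991 over genes, libraries of different groups with 0.814 to 0.852. All same-group pairs differed by more than sampling noise (mean chi-square per gene 4.79 to 23.4), which does not show that the replicates were independent.

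**Figure D2:**
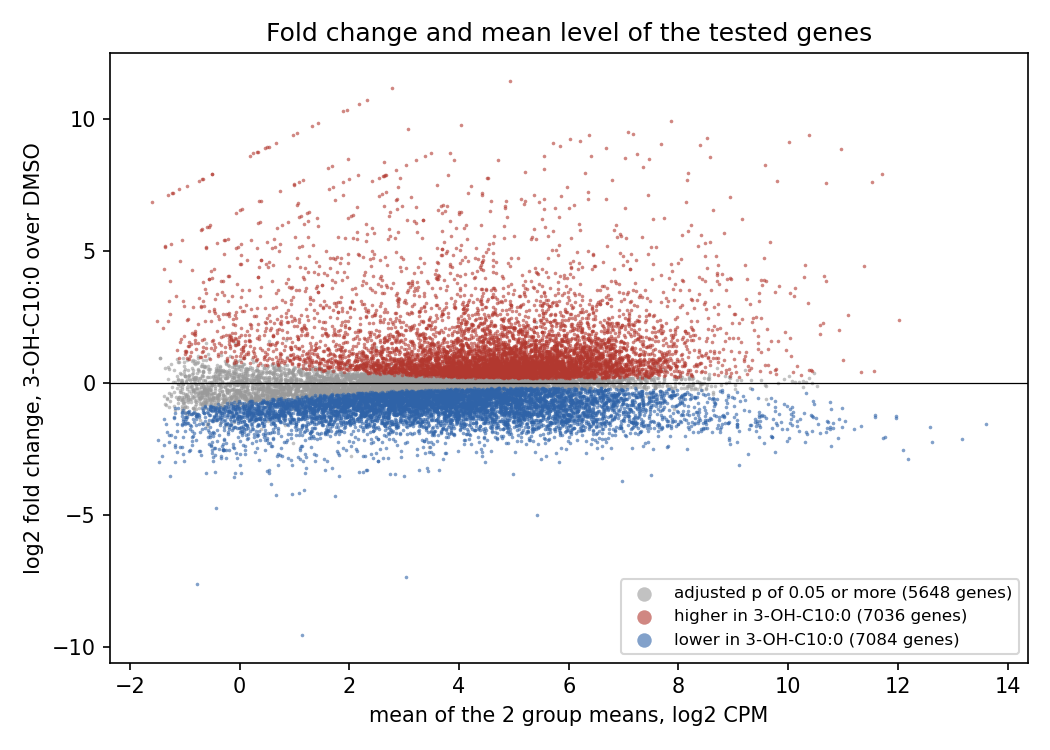
Log2 fold change of treated over DMSO (vertical axis) against the mean of both group means in log2 CPM (horizontal axis) for each tested gene. Red points are the 7036 genes that rose, blue points the 7084 genes that fell and grey points the 5648 genes with an adjusted p of 0.05 or more. The points reach further up than down, and the straight diagonal streaks at low level are genes without counts in DMSO, whose fitted fold change is no measured value.

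The genes with the largest increases were close to absent from the DMSO libraries. CRK20, a cysteine-rich receptor-like kinase (AT4G23280, chromosome 4, 12174733 to 12177576), had 1 count in the DMSO libraries and 3821 in the treated ones, a ratio of 3782 with a 95% counting interval of 678 to 149400. Its fitted log2 fold change of 11.44 became 13.31 without DMSO replicate 3, the library with that count. NIMIN1, a protein that binds the salicylic acid receptor NPR1, had no count in DMSO and was at least 280-fold higher in treated seedlings, against a floor of 3 counts over the group. By the same floor AT3G28510, a P-loop ATPase, was at least 206-fold higher, the receptor-like protein RLP20 at least 186-fold, AT1G57650 at least 161-fold, the assembled locus MSTRG.10963, which has no gene code, at least 156-fold, AT1G33950, of the avirulence-induced AIG1 family, at least 113-fold and AT5G37840 at least 107-fold. The glutathione transferase AT5G44990 had 2 counts in DMSO (ratio 1024, 95% counting interval 283 to 8461) and AT2G18680 had 1 (ratio 1049, 188 to 41480). Without DMSO replicate 2 their fitted log2 fold changes went from 9.77 to 12.43 and from 9.59 to 11.47. CYP82C2, a cytochrome P450 of indole cyanogenic metabolism, rose from 0.472 ± 0.203 to 466 ± 129 CPM, and the berberine bridge enzyme-like oxidase AT1G26410 from 0.369 ± 0.153 to 269 ± 47.1 CPM. CRK20 and AT1G26410 lie in clusters of similar genes, and reads could have been split among the copies.

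The 12 largest decreases were in genes of varied or unknown function. AT5G33370, a GDSL lipase, had 275 counts in DMSO and none in treated libraries, at least 92.6-fold lower against a floor of 3 counts over the group, and the peroxidase AT1G05250 was at least 24.6-fold lower. AGP30, an arabinogalactan protein of root cell walls, fell from 16.3 ± 4.11 to 0.101 ± 0.0581 CPM and FRO6, a ferric reductase of leaves, from 233 ± 54.5 to 17.7 ± 9.33 CPM. MES18, a methyl esterase, fell from 83.2 ± 7.78 to 2.33 ± 3.33 CPM. Its treated libraries stood at 0.255, 0.561 and 6.16 CPM, and without treated replicate 3 its log2 fold change went from -4.99 to -7.67. AT1G76955 had 3 counts in the treated libraries and 89 in DMSO (ratio 30.0 in favour of DMSO, 95% counting interval 9.93 to 148), with log2 fold changes of -4.75 over all libraries, -4.15 without DMSO replicate 1 and -5.64 without treated replicate 1. The others among the 12 were AT3G19430 (-4.28), the copper amine oxidase AT1G31690 (-4.24, and -5.67 without treated replicate 3), the lipid-transfer protein AT5G46900 (-4.22, adjusted p = 0.0112, 0.0747 without treated replicate 3, and log2 fold changes of -3.54 without DMSO replicate 1 and -5.30 without treated replicate 2), AT4G10955 (-4.15), the floral regulator ATC (-4.07, and -4.93 without treated replicate 3) and the anthocyanin regulator PAP2 (MYB90, -3.83, adjusted p = 0.0337). The PAP2 call was lost without any 1 of the treated libraries (adjusted p of 0.0915, 0.0967 and 0.148) and without the filter on low counts (0.0648), and its log2 fold change was -2.05 without DMSO replicate 1.

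Markers of pattern-triggered immunity rose almost as a whole. Of 31 measured, 30 rose and none fell, with 30 adjusted over the list alone, and the median log2 fold change was 3.08 (camera adjusted p = 4.8e-36, adjusted p = 0.0672 with an estimated correlation). FRK1, a receptor kinase used as a marker of flagellin responses, rose from 5.02 ± 1.40 to 1521 ± 249 CPM (8.24 ± 0.252, adjusted p = 2.8e-09). The peroxidase gene PER4 rose from 1.19 ± 0.215 to 734 ± 48.4 CPM, NHL10 from 1.31 ± 0.254 to 163 ± 7.89 CPM and the glutathione transferase GSTF6 from 30.4 ± 1.02 to 5863 ± 623 CPM. GSTF6 has the near-identical neighbour GSTF7, so the split between them is uncertain. The member that did not pass was PHI1 (0.78, adjusted p = 0.109).

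Salicylic acid genes rose, with an exception among the markers of its late response. Of 21 measured members of that list, 20 rose and 1 fell, with 20 and 1 adjusted over the list alone (median log2 fold change 3.80, camera adjusted p = 1.3e-21), and this was the only list whose call held with an estimated correlation (adjusted p = 0.0116). The biosynthetic genes ICS1 (6.94 ± 0.211 to 318 ± 23.6 CPM) and PBS3 (0.749 ± 0.124 to 302 ± 5.98 CPM), the salicylic acid hydroxylase DMR6 (10.1 ± 0.608 to 119 ± 6.94 CPM) and the receptor NPR3 (15.7 ± 2.099 to 137 ± 6.86 CPM) rose. PR5, a thaumatin-like pathogenesis-related protein, fell by 0.998 on the log2 scale (adjusted p = 0.00170). PR1, the common marker of salicylic acid output, rose from 6 to 89 counts (0.0952 ± 0.125 to 1.53 ± 1.35 CPM, log2 fold change 3.87 ± 0.989, adjusted p = 0.00823), with log2 fold changes of 5.63 without DMSO replicate 2 and 2.90 without treated replicate 2. PR2 did not pass the filter on low counts and was not tested.

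Genes of tryptophan-derived defence compounds rose: 22 of 23 were higher and 1 was lower, with 22 and 1 adjusted over the list alone (median 3.08, camera adjusted p = 2.4e-25, adjusted p = 0.0970 with an estimated correlation). The camalexin pathway gene CYP71A12 rose from 3.998 ± 0.831 to 2664 ± 197 CPM, although reads may have been shared with its neighbour CYP71A13. The anthranilate synthase genes ASA1 (33.9 ± 2.09 to 499 ± 30.5 CPM) and ASB1 (15.7 ± 0.942 to 217 ± 12.7 CPM) and the indole glucosinolate hydroxylase CYP81F2 (2.64 ± 0.642 to 258 ± 12.1 CPM) rose as well. PAD3, which makes camalexin in the last step of the pathway, rose from 2.08 ± 0.785 to 10.2 ± 1.11 CPM (2.29 ± 0.225, adjusted p = 6.4e-06). The member that fell was MYB34 (-1.502), a regulator of indole glucosinolate genes. On the list of aliphatic glucosinolates 3 of 15 rose and 10 fell, with 3 and 10 adjusted over the list alone (camera adjusted p = 0.174, and 0.0326 without treated replicate 1). The regulator MYB28 (-1.90) and the glucosyltransferase UGT74C1 (-1.49) fell, while the sulfotransferase SOT17 (2.97) and the oxygenase FMOGS-OX1 (3.45, and 4.36 without DMSO replicate 1) rose, and 6 in place of 10 members fell without treated replicate 3.

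Ethylene genes rose in part. Of 22 measured, 13 rose, none fell and 9 did not pass, with 13 adjusted over the list alone (median 0.60, camera adjusted p = 1.7e-04, adjusted p = 0.135 with an estimated correlation). The members that rose most were the 1-aminocyclopropane-1-carboxylate synthase genes ACS8 (0.146 ± 0.133 to 52.0 ± 5.56 CPM, log2 fold change 8.45 and 9.41 without DMSO replicate 1) and ACS2 (0.749 ± 0.139 to 58.0 ± 4.27 CPM). ACS7 rose from 23.6 ± 3.81 to 150 ± 13.1 CPM and the transcription factor ERF1 from 0.601 ± 0.299 to 8.86 ± 0.826 CPM, whereas EIN2, a transducer of the ethylene signal, and the defensin PDF1.2A did not pass (-0.05, adjusted p = 0.63, and 0.35, adjusted p = 0.59). On the jasmonate list 11 of 26 rose and 1 fell, and 9 and 1 adjusted over the list alone, and the list did not pass the set test (camera adjusted p = 0.238). LOX4 (1.65 ± 0.773 to 41.8 ± 9.49 CPM), JAZ1 (8.39 ± 2.47 to 61.1 ± 2.71 CPM), LOX3 and OPR3 rose, AOC2 fell by 1.73, and the response genes VSP1 (0.76, adjusted p = 0.49), VSP2 (-0.34, adjusted p = 0.61) and MYC2 (0.17, adjusted p = 0.63) did not pass. LOX2 and CORI3, named after their values were seen, did not pass either and stood apart in DMSO replicate 1. There LOX2 was at 46.4 CPM against 7.89 and 11.4 in the other DMSO libraries, and CORI3 at 5.10 against 0.425 and 0.556. Without that library the list still had 11 members that rose and 1 that fell (camera adjusted p = 0.179).

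Detoxification genes that respond to electrophiles and xenobiotics rose. Of 20 measured, 15 rose and 1 fell, with 15 and 1 adjusted over the list alone (median 2.29, camera adjusted p = 5.6e-06, adjusted p = 0.135 with an estimated correlation). CYP81D8 rose from 1.33 ± 0.402 to 44.9 ± 3.96 CPM, the alkenal reductase gene AER from 146 ± 16.1 to 895 ± 85.0 CPM and GSTU24 from 1.499 ± 0.399 to 22.8 ± 3.62 CPM, while the glutathione transferase GSTU5 fell by 0.81 on the log2 scale. Antioxidant genes split: 6 of 15 rose and 5 fell, with the same adjusted over the list alone. The cytosolic ascorbate peroxidase APX1 (624 ± 48.6 to 3714 ± 534 CPM), the alternative oxidase AOX1A (19.1 ± 2.18 to 133 ± 14.0 CPM), GR1, CAT1, CSD1 and DHAR2 rose. The members that fell were the plastid enzymes PRXQ (-1.69), NTRC (-0.92) and GR2 (-0.80), the peroxisomal catalase CAT2 (-0.63) and DHAR1 (-0.39). The median of this list (-0.12) had the opposite sign to its mean (0.56) and to the direction of its test (camera adjusted p = 0.317).

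Phenylpropanoid and lignin genes rose: 15 of 17 were higher and 2 lower, with 15 and 2 adjusted over the list alone (median 2.28, camera adjusted p = 8.3e-10, adjusted p = 0.317 with an estimated correlation). PAL1, which opens the pathway, rose from 110 ± 25.4 to 2417 ± 232 CPM, C4H from 185 ± 14.2 to 3037 ± 259 CPM, COMT1 from 181 ± 8.45 to 1905 ± 347 CPM and the cinnamyl alcohol dehydrogenase CAD5 from 15.7 ± 0.601 to 356 ± 64.9 CPM. The members that fell were PAL3 (-1.71), a minor phenylalanine ammonia-lyase, and 4CL3 (-1.58), the 4-coumarate:CoA ligase linked to flavonoids. Flavonoid and anthocyanin genes were lower: 8 of 9 measured fell and none rose, with 8 adjusted over the list alone (median -1.25, camera adjusted p = 0.0306, adjusted p = 0.519 with an estimated correlation). Chalcone synthase CHS fell from 214 ± 36.5 to 98.4 ± 12.6 CPM, F3H from 30.9 ± 5.05 to 13.6 ± 1.03 CPM and the regulator MYB111 from 3.37 ± 1.12 to 0.446 ± 0.105 CPM. The call of this list was lost without treated replicate 3 (adjusted p = 0.0761) and in limma on FPKM values (0.0836 to 0.110). Late anthocyanin genes, chosen after their values were seen, stood apart in DMSO replicate 1. There LDOX, which was not tested, had 209 counts against 9 and 11 in the other DMSO libraries. Without that library the list gave a camera adjusted p of 0.0139. Genes outside the list stood apart in it too, such as FRO2 (365 counts against 39 and 107) and LSU1 (112 against 18 and 13). Its pairs with the other DMSO libraries had a mean chi-square per gene of 13.5 and 12.2, against 6.19 for the remaining DMSO pair.

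Genes of fatty acid breakdown and synthesis moved in opposite directions. Of 18 measured genes of peroxisomal beta-oxidation and the glyoxylate cycle, 14 rose and 4 fell, with 14 and 4 adjusted over the list alone (median 0.97, camera adjusted p = 0.00336, adjusted p = 0.441 with an estimated correlation). The acyl-CoA synthetases LACS7 (20.11 ± 0.102 to 130 ± 14.0 CPM) and LACS6 (87.9 ± 3.59 to 327 ± 13.2 CPM), the multifunctional protein MFP2 (95.7 ± 7.55 to 285 ± 5.93 CPM) and the thiolase KAT2 (285 ± 14.2 to 842 ± 20.13 CPM) rose. The members that fell were the peroxisomal malate dehydrogenase PMDH2 (-2.06), the second thiolase gene KAT5 (-1.33), malate synthase MLS (-1.03) and the acyl-CoA oxidase ACX5 (-0.34). Of 19 genes of fatty acid synthesis and desaturation, 17 fell and 1 rose, with 17 and 1 adjusted over the list alone (median -0.80, camera adjusted p = 4.8e-05, adjusted p = 0.284 with an estimated correlation). The desaturases FAD8 (88.0 ± 2.19 to 25.4 ± 2.97 CPM) and FAD3 (107 ± 5.62 to 51.4 ± 3.11 CPM), the acyl carrier protein ACP4 (233 ± 6.14 to 99.01 ± 6.61 CPM) and the enoyl reductase MOD1 (164 ± 3.29 to 71.5 ± 8.36 CPM) fell, and the thioesterase FATB rose by 0.34.

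Photosynthesis genes fell. Of 27 measured members, 24 fell, none rose and 3 did not pass, with 24 adjusted over the list alone (median -1.60, camera adjusted p = 1.5e-10, adjusted p = 0.206 with an estimated correlation). PSBO2 of the oxygen-evolving complex fell from 1256 ± 49.1 to 259 ± 64.2 CPM, LHCA3 from 2672 ± 176 to 806 ± 87.8 CPM, PSBS from 966 ± 91.0 to 289 ± 26.0 CPM and Rubisco activase RCA by 2.23 on the log2 scale. LHCB1.1 (-0.97), LHCB2.1 (-0.32) and LHCB2.2 (-0.62) did not pass, and the RBCS and LHCB1 copies and PSBO1 and PSBO2 are similar enough to share reads. Root markers were lower in the same libraries: 8 of 13 fell and 2 rose, with 9 and 2 adjusted over the list alone (median -0.70, camera adjusted p = 0.175), among them the epidermal regulator WER (-1.54) and the glucosidase PYK10 (1303 ± 53.2 to 710 ± 148 CPM). Without DMSO replicate 1 only 1 root marker and 1 vascular marker rose. Of 8 vascular genes measured, 6 fell and 2 rose, with the same adjusted over the list alone (camera adjusted p = 0.213): the xylem genes XCP1, XCP2, IRX1, IRX3 and IRX5 and the phloem protein gene PP2-A1 fell, while the phloem genes SUC2 (177 ± 6.47 to 299 ± 18.6 CPM) and APL rose. Of 6 guard cell genes 3 fell (MYB60, EPF1 and SLAC1) and none rose, with 3 adjusted over the list alone (camera adjusted p = 0.264), and the SLAC1 call was lost without DMSO replicate 1 (adjusted p = 0.0646) and without treated replicate 1 (0.0597).

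All 19 measured cell division genes fell, with 19 adjusted over the list alone (median -0.88, camera adjusted p = 3.5e-04, adjusted p = 0.345 with an estimated correlation). CDC20.1, an activator of the anaphase-promoting complex, fell from 50.5 ± 3.63 to 21.1 ± 1.89 CPM, CYCD3-1 from 24.3 ± 2.02 to 12.8 ± 0.596 CPM and the cytokinesis syntaxin KNOLLE from 27.7 ± 2.38 to 15.3 ± 0.0504 CPM. Of 7 senescence genes 6 rose and 1 fell, with 6 and 1 adjusted over the list alone (median 1.31, camera adjusted p = 0.00694, adjusted p = 0.345 with an estimated correlation). SAG13 rose from 0.429 ± 0.0452 to 169 ± 43.5 CPM, SAG21 from 114 ± 20.7 to 629 ± 54.7 CPM and the chlorophyll breakdown gene SGR1 from 19.4 ± 1.94 to 42.7 ± 2.29 CPM, whereas NYC1, a chlorophyll b reductase, fell from 610 ± 59.6 to 323 ± 39.3 CPM. Of 18 heat and protein folding genes 12 rose and none fell, with 12 adjusted over the list alone (median 1.42, camera adjusted p = 5.1e-04, adjusted p = 0.441 with an estimated correlation). Members that rose included BIP3 (0.272 ± 0.0813 to 20.04 ± 3.80 CPM), SDF2 (35.4 ± 3.74 to 138 ± 17.56 CPM) and PDIL1-1 (122 ± 11.3 to 452 ± 42.6 CPM), which fold proteins in the endoplasmic reticulum, and HSP90.1 (3.87), while the small heat shock genes HSP17.4, HSP17.6A, HSP17.6II, HSP18.2, HSP21 and HSP22 did not pass.

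**Figure D3:**
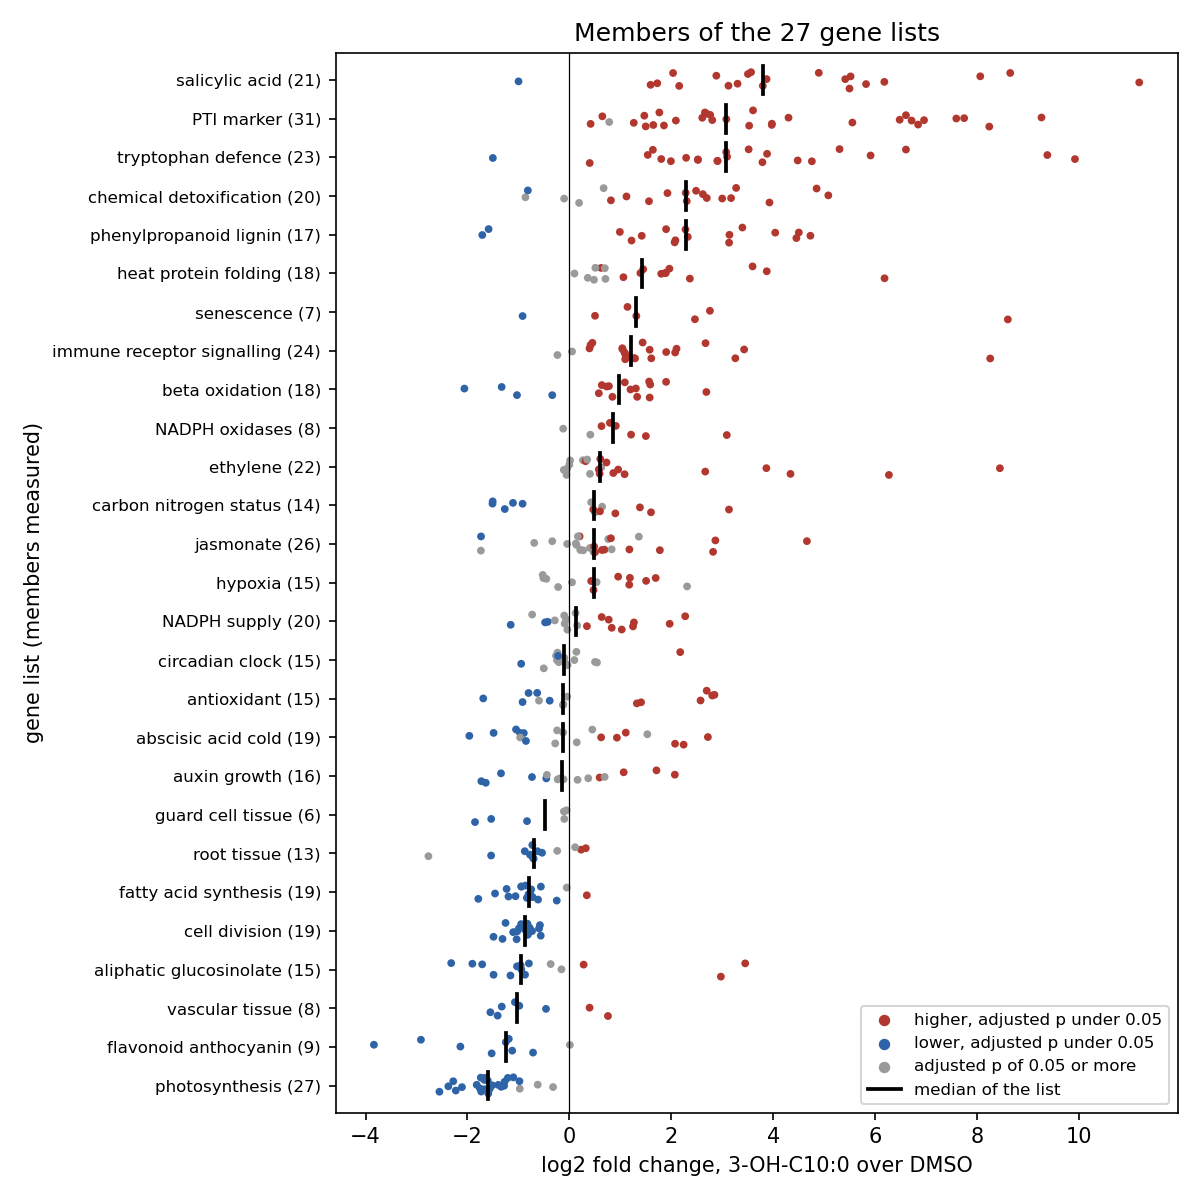
Log2 fold change of treated over DMSO (horizontal axis) for each measured member of the 27 gene lists (vertical axis, number measured in brackets), sorted by list median. Points are genes, coloured by whether they rose, fell or did not pass an adjusted p of 0.05, and black bars are list medians. Medians run from 3.80 for salicylic acid to -1.60 for photosynthesis.

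The remaining 5 lists did not pass the set test. Of 15 circadian clock genes 1 rose and 2 fell, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.497). Without DMSO replicate 1 the count that fell was 5. RVE8 rose from 0.804 ± 0.287 to 3.73 ± 1.803 CPM, and CHE fell by 0.95. FKF1 fell by 0.22 (adjusted p = 0.0164), a call lost in DESeq2 (0.0652) and without treated replicate 2 (0.0621). CCA1 (0.50, adjusted p = 0.39), LHY (-0.23, adjusted p = 0.80) and TOC1 (-0.04, adjusted p = 0.76) did not pass. On the abscisic acid and cold list 6 of 19 rose and 6 fell, and 5 and 3 adjusted over the list alone (camera adjusted p = 0.715). ABI1 (0.93), HAI1 (2.07) and NCED3 (2.24) rose and ERD10 (-0.85) fell. Of 15 hypoxia genes 8 rose, none fell and 7 did not pass, with 8 adjusted over the list alone (camera adjusted p = 0.317), and without treated replicate 3 there were 7 that rose and 1 that fell. LBD41, a hypoxia-induced transcription factor named after its values were seen, stood apart in that library (147 CPM against 31.6 and 32.7 in the other treated libraries) and did not pass (2.31, adjusted p = 0.0782). Its DMSO libraries stood at 7.18, 10.1 and 25.6 CPM. Over all settings its log2 fold change ran from 1.17 to 3.02, and it passed in 5 of 19. ALAAT1 rose from 143 ± 6.54 to 406 ± 11.9 CPM. Of 16 auxin and growth genes 4 rose and 5 fell, with the same adjusted over the list alone (camera adjusted p = 0.743). GH3.2 (2.07) and GH3.5 (1.06) rose and the expansins EXPA1 (-1.64) and EXPA8 (-1.73) fell. Of 14 carbon and nitrogen status genes 6 rose and 5 fell, and 8 and 5 adjusted over the list alone (camera adjusted p = 0.715). The nitrate reductase gene NIA2 rose from 446 ± 15.1 to 1353 ± 122 CPM, while nitrite reductase NIR1 (-1.505) and the transporter NRT1.1 (-1.11) fell. DIN9 rose as well, with log2 fold changes of 2.97 to 3.24 when a library was left out. Median and mean differed in sign for the clock (-0.10 and 0.04) and for abscisic acid and cold (-0.12 and 0.16), and the camera test pointed down for both.

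Organelle-encoded loci took 0.00925% ± 0.00127 of the counts in DMSO and 0.00789% ± 0.00120 in treated libraries (n = 3 each, exact permutation test, two-sided p = 0.3). The 843 loci assembled by the submitters without a gene code took 0.201% ± 0.00348 of the counts in DMSO and 0.230% ± 0.00821 in treated libraries (n = 3 each, exact permutation test, two-sided p = 0.1, the smallest possible here).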

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

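Total-count scaling, leaving out assembled loci, the GC and length correction and the list counts without single doubted libraries were added after the data were examined, and all other settings were fixed before. The counts of 7036 genes that rose and 7084 that fell ranged from 6143 to 7226 and from 6481 to 8158 over scalings, filters, tests and units, and from 6618 to 6922 and from 6530 to 6849 when a library was left out. Requiring at least 2-fold left 3107 and 2913 genes, and an adjusted p under 0.01 left 6136 and 5782. The balance of 2-fold calls turned to lower with the GC and length correction (2733 and 3634), total-count scaling (2878 and 3343) and in limma on FPKM with pseudocounts of 0.1 (2711 and 2882) and 0.01 (2742 and 3009), but not of 1 (2451 and 2066). No filter gave 7220 and 7091, a minimum count of 50 gave 6379 and 6557, the DESeq2 Wald test 6916 and 6481, total-count scaling 6410 and 7732 and limma on FPKM with a pseudocount of 1 6282 and 7279. The GC and length correction gave 6143 and 8158 and moved the median log2 fold change of all tested genes from -0.0379 to -0.163, which shifts calls toward lower. A block for the replicate number gave 7063 and 7087, with correlations of the same-number libraries of 0.0264, -0.0159 and 0.0994. In all 6 fits that left out a library, 6223 genes stayed higher and 5929 stayed lower.

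The number of lists past the set test was 14 in the main setting, 1 with an estimated correlation, 22 with fry and 13 to 15 when a library was left out. With an estimated correlation the adjusted p was 0.116 for immune receptors and signalling, 0.0672 for markers of pattern-triggered immunity, 0.1351 for ethylene and for detoxification, 0.0970 for tryptophan-derived defence, 0.4407 for beta-oxidation and for heat and protein folding, 0.2839 for fatty acid synthesis, 0.3169 for phenylpropanoids, 0.5193 for flavonoids, 0.2062 for photosynthesis and 0.3448 for cell division and for senescence. Lists that passed with fry but not with camera in the main setting were NADPH supply (0.000233), NADPH oxidases (0.000207), jasmonate (0.00406), antioxidants (0.000207), hypoxia (0.00718), root tissue (0.00123), guard cells (0.00372) and vascular tissue (0.00761). Of these, NADPH oxidases also passed preranked camera after the GC and length correction (0.0283). Fry asks whether the members changed at all, not whether they changed more than other genes. Flavonoids did not pass in limma on FPKM with pseudocounts of 1, 0.1 and 0.01 (0.110, 0.0838 and 0.0836), and ranged from 0.00357 to 0.0761 when a library was left out, lost without treated replicate 3. Aliphatic glucosinolates ranged from 0.0326, passing without treated replicate 1, to 0.3. The cause was not tested for these changes. Over lists and settings 513 results stayed on their side of the threshold, called or not, 10 passed only in the alternative and 17 were lost. Over the genes that the naming rule took these were 2420, 3 and 10, and none reversed in either. The difference in organelle share was -0.00136 percentage points (-0.00198 to -0.000713 when a library was left out) and 9.667e-05 for mitochondrial loci alone, the opposite sign, with neither past the exact test.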

Other observations

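The families below and all explanations and tests in this part were chosen after the results were seen. Among families grouped by product name, WRKY transcription factors, which regulate defence genes, rose in 46 of 58 and fell in 4 (median log2 fold change 2.22, camera adjusted p = 5.7e-13), with WRKY8 going from 0.364 to 32.6 CPM. Berberine bridge enzyme-like oxidases, which act in cell wall and indole metabolism, rose in 14 of 20 (median 3.90, camera adjusted p = 5.7e-13), and AT1G30700 went from 8.81 to 1769 CPM. Cysteine-rich receptor-like kinases rose in 28 of 37 and fell in 4. The group matched as lectin receptor kinases, which may take in malectin-like kinases such as AT5G39000, rose in 42 of 68 and fell in 17. Intracellular resistance proteins of the NBS-LRR type rose in 96 of 146 and fell in 12. Of 52 proteasome subunits 47 rose, including the activator PA200, from 41.0 to 197 CPM. None of these families passed with an estimated correlation, where the smallest adjusted p was 0.0646.

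Several families fell in most of their members. Ribosomal proteins, cytosolic and organellar in a single group, fell in 228 of 264 and rose in 11 (median -0.69, camera adjusted p = 5.9e-13, adjusted p = 0.280 with an estimated correlation), and all 4 proteins named as chloroplast ribosomal fell. Pentatricopeptide repeat proteins, which process organelle transcripts, fell in 170 of 239 and rose in 7 (adjusted p = 0.160 with an estimated correlation). Aquaporins fell in 16 of 20, expansins and xyloglucan endotransglucosylases in 32 of 48 and histones in 27 of 43, with adjusted p = 0.354, 0.314 and 0.352 with an estimated correlation. SIP1;2 went against the aquaporins (2.78) and HTA12 against the histones (1.49). Cytochromes P450 split, with 62 higher and 59 lower of 173.

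Lower photosynthesis transcripts (median -1.60) were weighed against 3 technical explanations, with tests chosen after the result was seen. Less green tissue might lower them, and root markers would then rise if the treatment itself left those unchanged. The root median did not rise, at -0.7012 (bootstrap 95% interval over genes, -0.7736 to -0.2391). However, 71.4% of the tested genes passed the threshold, so a direct fall of root markers could hide a shift in tissue. Less green tissue therefore stays open. A different time of day at harvest could lower photosynthesis transcripts, but the clock genes moved by a median absolute log2 fold change of 0.233 (0.1015 to 0.503), against 1.60 for photosynthesis. The scaling of the libraries or a GC and length trend may shift a median. Over the scalings used here and that correction, the least negative median was -1.528, relative to the other genes. Reduced transcription and faster decay stay open as hypotheses, because total RNA at a single time cannot tell them apart.

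Treated replicate 3 lay closer to DMSO than the other treated libraries, by 10.5% of the difference for lowered genes and 12.38% (11.48 to 13.3) for raised genes, and all tests of it were chosen after the result was seen. After random thinning to the smallest library, 10.31% remained for lowered genes. Thinning keeps the expected share of each gene in the counts and so could hardly change this median, and it does not decide whether depth played a part. A response smaller by a single factor on the log scale could not explain the pattern, because genes lowered 4-fold or more lay 12.6% toward DMSO against 6.483% predicted. An admixture of RNA or tissue without the response would give 1 share throughout, but shares were 26.22% (22.6 to 40.94) for heat and protein folding and 23.79% (14.84 to 28.69) for phenylpropanoids against 1.494% (-2.346 to 9.294) for tryptophan-derived defence, and 9.356% (8.918 to 9.795) for genes lowered 2- to 4-fold against 12.6% (11.91 to 13.1) for those lowered further. Genes raised 2- to 4-fold and further gave overlapping shares, 11.33% (10.55 to 12.3) and 12.52% (11.81 to 13.54). List medians spread about as much in the other treated libraries (SD 10.01 against 7.652 and 10.39). Some lowered genes lay below such a share, such as AGP30 (0.0383 CPM against a DMSO mean of 16.3) and AT5G33370, without a count in any treated library. Others lay near it (ATC 0.421 against 4.27, AT1G31690 0.306 against 3.03, MES18 6.16 against 83.2). These genes are examples and not a tally of the largest decreases. Admixture, unresponsive seedlings and other causes stay open.

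That 71.4% of the tested genes passed was weighed last, with tests chosen after the result was seen. Of 10 splits of the libraries 1, the true grouping, called 14120 genes and the highest other called 0 (137 at an unadjusted p under 0.05). Every other split mixed treated and DMSO libraries on both sides, so the treatment difference entered its within-group spread and calls were unlikely from the start. In addition, 10 splits are too few to give a share under 0.05, so the splits decide nothing here. A GC and length trend might have caused calls, but 13133 stayed in the same direction after the correction. The choice among the scalings used here did not make most calls, as 13494 stayed under the scaling that kept fewest. These scalings are all set from the measured genes and moved the median log2 fold change only between -0.0149 and -0.123. A shift shared by most genes would stay hidden under each of them. The near balance of genes that rose and fell therefore depends on the scaling. Whether the breadth reflects the dose, given as 5 microM or as 5 mM, stays open.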
